A study of Mus musculus with 45 samples.

How the data were processed

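Gene-level values were taken from the deposited results files, 1 per library, each with the same 23420 genes. The expected counts are reads per gene as estimated by RSEM, deposited by the authors without further normalization per the file headers, and 9.09% of them were not whole numbers. The TPM values were scaled by RSEM before deposit to a fixed sum per library over all genes, per the file headers, and were used only for a second permutation test of Bag6. The labels name bcl2fastq and RSEM without versions. Genome build, aligner and annotation release are not given in the sources used here, so no coordinates are reported. Gene names, chromosomes and gene order came from a RefSeq table of GRCm38.p6, in which 23068 genes were found by transcript and 224 by symbol, and 128 were not found. Genes with near-identical copies, among them the MHC class I relatives and Rps27, are reported as uncertain.

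Per the labels, bone marrow cells were cultured with 20 ng/ml GM-CSF, live CD11c-high cells were sorted on day 9, and libraries were made from 1 µg of total RNA. The labels give 1 protocol and 5 biological replicates per group, and name no vehicle group. Total expected counts per library ran from 1509219 to 4737736. The ribosomal RNA precursor Rn45s took 8.39% to 12.73% of them, and no mitochondrially encoded gene had a row.

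Differential expression was tested with edgeR 4.0.16 and limma 3.58.1 in R 4.3.3. Expected counts were rounded to whole numbers and scaled by TMM factors. The 10287 genes kept by filterByExpr were tested two-sided by a robust quasi-likelihood F test, with group means of all 45 libraries in 1 fit. The fit had 36 residual degrees of freedom and a common dispersion of 0.037. Genes with a Benjamini-Hochberg adjusted p under 0.05 within a comparison were called. Standard errors (SE) of log2 fold changes were derived from the F statistic and carry both counting error and the spread between libraries. CPM are counts scaled to library size with TMM factors, and no other interval is given. DESeq2 1.42.0 served as a second tool.

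Of the comparisons, 14 were chosen before the data were examined, as were the genes' naming rule, the lists and most alternatives, and 4 comparisons of inhibitor with LPS groups were added after. The naming rule took, in each comparison of 2 groups, called genes with a mean of at least 10 CPM in the higher group and no overlap between the libraries of both groups. From these it took the 10 with the largest positive and the 10 with the largest negative log2 fold change. For interactions it took called genes with at least 10 CPM in the highest group, the 6 largest each way. Members of the fixed lists, Bag6 and the 10 genes with the largest mean change among those called alike in all 4 genotype comparisons could be named too.

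Before the data were examined, 46 lists were fixed, 32 of gene groups and 14 of cell markers. Of their genes, 18 had no row in the files. Lists were tested with camera at a preset correlation of 0.01, adjusted over 720 tests, 40 lists in 18 comparisons, and 164 tests passed. With the correlation estimated for each list 24 passed, and fry, which asks whether a list's genes move one way on balance, passed 207. Of the lists, 2 had no tested member, 3 had 1 or 2, and 1 had no gene in the files.

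Whether replicate numbers pair libraries was judged from 2000 abundant genes, a comparison pairing where every same-numbered correlation of deviations from the group mean exceeded 0.1. This held for KO LPS, KO 4µ8C and KO 4PBA against KO medium, WT 4PBA against WT medium, KO 4µ8C against KO LPS, and 4PBA against LPS in both genotypes. Correlations there ran from 0.19 to 0.70, and values blocked by replicate are given beside these comparisons where they differ.

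A self-test on simulated counts with the design, depth and spread of KO medium against WT medium (10223 genes) recovered 50.7% of 67 genes changed 1.5-fold, 82.1% of 67 changed 2-fold and 100% of 66 changed 4-fold. With position as a term it recovered 25.4%, 62.7% and 100%. Of 10003 unchanged genes 6 were called, 3.6% of 167 calls. A planted list of 20 genes changed 1.5-fold gave camera adjusted p = 3.4e-13, and 0 of 40 unchanged lists were called by camera. In a simulation with a position effect on 350 genes and no genotype change, 114 of all genes in the fit were called without the term. With the term 0 were called in edgeR.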

Results

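RNA was sequenced from 45 libraries of mouse dendritic cells grown from bone marrow with GM-CSF, in 9 groups of 5 biological replicates. The labels name the cells wild type (WT) or floxed for Bat3 with CD11c-driven Cre (KO). Bat3 is an older name of Bag6, which encodes a cytosolic chaperone for proteins with exposed hydrophobic segments. WT and KO cells were kept in medium or given lipopolysaccharide (LPS), 4µ8C or 4PBA for 8 h, and WT cells were also given rapamycin. LPS is the bacterial ligand of Toll-like receptor 4, and 4µ8C blocks the RNase of IRE1, a sensor of stress in the endoplasmic reticulum (ER). 4PBA, 4-phenylbutyrate, is a chemical chaperone that also inhibits histone deacetylases, and rapamycin inhibits the growth kinase complex mTORC1. The labels name 1 treatment per group, and they do not state whether LPS was added together with 4µ8C, 4PBA or rapamycin. Total expected counts per library ran from 2876792 to 4233895 in WT medium, 1956436 to 3959531 in WT LPS, 1509219 to 3070058 in WT 4µ8C, 2098083 to 3842844 in WT 4PBA and 1977656 to 3821847 in WT rapamycin. In KO cells they ran from 2501893 to 4312080 in medium, 2734191 to 4737736 with LPS, 2358098 to 4416885 with 4µ8C and 1945718 to 4081185 with 4PBA. Of 23420 genes in each file, 10287 had enough counts to be tested.

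Bag6, the targeted gene, had lower mean CPM in KO than in WT cells under each of the 4 shared treatments. No difference passed the edgeR test across all genes. In medium the mean was 14.4 ± 2.16 CPM in WT and 9.22 ± 2.83 in KO (SD, n = 5 each; log2 fold change -0.65, SE 0.23, edgeR adjusted p = 0.072, exact permutation p = 0.024). With LPS it was 13.9 ± 1.95 and 9.28 ± 4.39 CPM (-0.59, SE 0.25, edgeR adjusted p = 0.18, permutation p = 0.056). With 4µ8C it was 12.7 ± 2.48 and 9.75 ± 2.89 CPM (-0.40, SE 0.25, edgeR adjusted p = 0.52, permutation p = 0.1). With 4PBA it was 14.6 ± 3.55 and 7.53 ± 2.85 CPM (-0.91, SE 0.25, edgeR adjusted p = 0.072, permutation p = 0.016). The permutation tests were two-sided over 4 treatments, and the smallest p they allow is 0.0079. Bag6 lay below every WT library of the same treatment in 4 of 5 KO libraries in medium, LPS and 4PBA and in 3 of 5 with 4µ8C. The libraries labelled KO replicate 4 held the highest Bag6 of their group each time, at 13.7, 14.9, 14.6 and 12.4 CPM in medium, LPS, 4µ8C and 4PBA, against means of 8.10, 7.89, 8.54 and 6.31 CPM in the other 4. Without KO replicate 4 the log2 fold change was -0.86 in medium, -0.79 with LPS and -1.21 with 4PBA, and all 3 passed the edgeR test. This removal, chosen afterwards, builds in a larger drop. Without KO_4u8C replicate 4 it was -0.59 and did not pass. The labels do not name the floxed exons, so counts can include reads from exons left in place. Bag6 had only 8 to 77 counts per library.

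**Figure D1:**
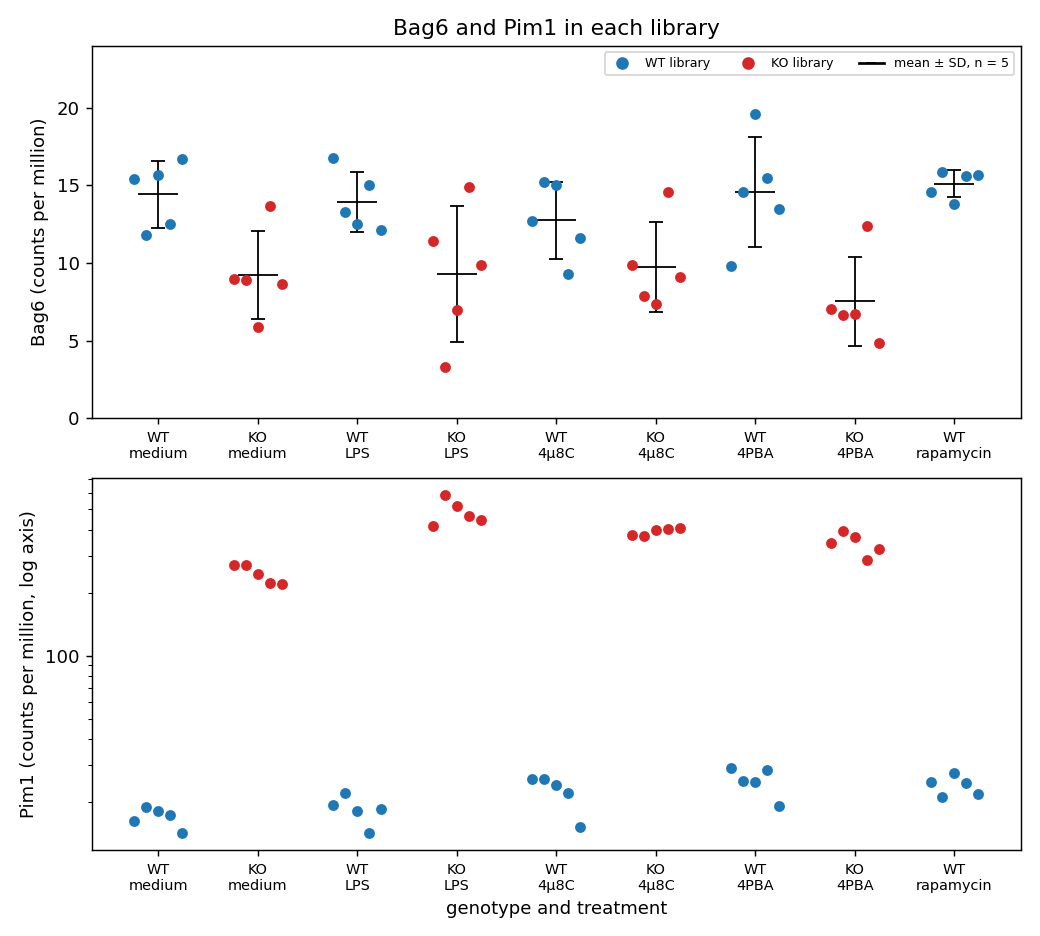
CPM of Bag6 (linear axis, with mean and SD of 5 libraries as bars) and of Pim1 (log axis) in each library, by genotype and treatment. Bag6 ran from 9.26 to 19.6 CPM in WT and from 3.30 to 14.9 in KO libraries, and Pim1 was higher in every KO library than in any WT library.

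The labels give each library a letter and number code, read here as a plate position, which they do not state. Codes at the edge (row A, columns 1 and 12) held all 5 WT medium and all 5 WT LPS libraries, none of the KO medium, WT 4PBA or KO 4PBA libraries, and 1 of 5 KO LPS libraries. WT 4µ8C, KO 4µ8C and rapamycin held 2 each, so 17 libraries were outer and 28 inner. Within the 4 groups that held both kinds (7 outer and 13 inner libraries), 350 of 9557 genes differed by position in edgeR, and 343 of them were lower in outer libraries. Among these was Rnf187, a RING-type ubiquitin ligase (log2 fold change outer against inner -2.52, SE 0.22, edgeR adjusted p = 1.4e-07). The heparanase Hpse, named after its value was seen, was another (-1.59, SE 0.12, edgeR adjusted p = 2.4e-10). Counts with position as a term, chosen after seeing the data, therefore stand beside the others. WT codes ran from A1 to E2 and KO codes from E3 to G8, so an outer or inner term cannot separate genotype from plate order.

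**Figure D2:**
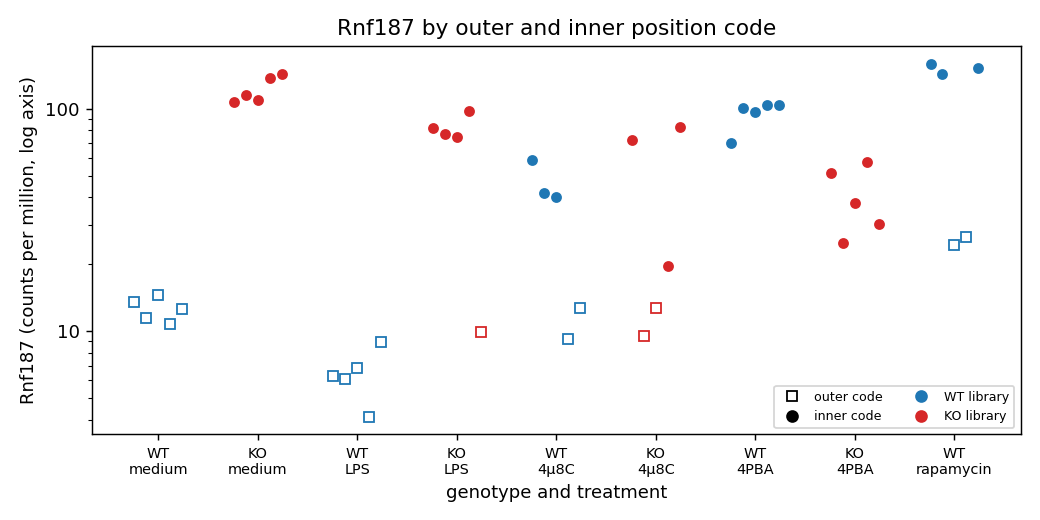
Rnf187 CPM (log axis) in each library, with open squares for outer position codes and filled circles for inner codes. In KO LPS, the 1 outer library held 9.86 CPM and the 4 inner libraries 74.8 to 97.8.

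KO against WT cells in medium asked which genes differed without added stimulus. Pim1, a serine/threonine kinase induced by cytokine signals, was 14.5-fold higher in KO cells (log2 fold change 3.86 ± 0.14 SE, 5 libraries per group, adjusted p = 1e-28). On the same scale, higher genes included Cebpb (3.51), a myeloid transcription factor, Rnf187 (3.28), Phlda3 (3.13), a p53-induced repressor of Akt, and Uck2 (3.06), a pyrimidine salvage kinase. Syap1 (3.27), Ndnl2 (3.24), Marcksl1 (3.18), Gpatch3 (3.10) and Tpst1 (2.96) were higher too, Ndnl2 being a subunit of the SMC5/6 complex, Marcksl1 an actin-binding protein and Tpst1 a protein tyrosine sulfotransferase (SE at most 0.65, adjusted p at most 0.00019). Lower in KO cells were the complement C1q chains C1qa (-1.94) and C1qb (-1.51), H2-T23 (-1.73), a non-classical MHC class I gene whose count is uncertain here and below because of close relatives, the paired immunoglobulin-like receptor Pira2 (-1.46) and Grn (-1.16), which encodes progranulin. Also lower were Ifitm1 (-1.45), an interferon-induced membrane protein, Fam213b (-1.33), a prostaglandin F synthase, Nptn (-1.32), an adhesion molecule, and Padi4 (-1.26), which citrullinates histones. Cxcr2 (-1.20), a receptor for neutrophil chemokines, and Ide (-1.08), the insulin-degrading enzyme, were lower as well (SE at most 0.35, adjusted p at most 0.0024).

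Of the inflammatory cytokine list in medium, 5 of 19 members were higher and 0 lower (7 and 0 adjusted over the list alone). The list's mean log2 CPM was 4.79 in KO_medium replicate 1 and 3.77 to 4.14 in the other KO libraries. WT libraries ran from 3.41 to 4.14. The list had camera adjusted p = 0.0041 (0.46 with an estimated correlation). The higher members included Tnfsf15 (1.18 ± 0.23), Il1b (0.90 ± 0.27), Il1a (0.72 ± 0.22) and Il1rn (0.51 ± 0.14), where Il1rn encodes the antagonist of the interleukin-1 receptor. Among NF-kB feedback genes, 5 of 20 members were higher and 0 lower (8 and 0 adjusted over the list alone), with Nfkbiz (0.80 ± 0.17) and Tnfaip3 (0.79 ± 0.25) as examples. The NF-kB feedback list had camera adjusted p = 0.0015 (0.52 with an estimated correlation). For interferon-stimulated genes, 3 of 24 members were higher and 0 lower (5 and 0 adjusted over the list alone), with Cmpk2 (1.20 ± 0.36) and Rsad2 (1.03 ± 0.34). The interferon list had camera adjusted p = 0.037 (0.9 with an estimated correlation). In oxidative phosphorylation, 0 of 23 members were higher and 3 lower (0 and 9 adjusted over the list alone), as for Cox5b (-0.46 ± 0.12) and Ndufa1 (-0.47 ± 0.13). The oxidative phosphorylation list had camera adjusted p = 5.4e-05 (0.46 with an estimated correlation). For cytosolic ribosomal proteins, 1 of 32 members were higher and 0 lower (1 and 0 adjusted over the list alone). The ribosomal protein list had camera adjusted p = 0.00025 (0.83 with an estimated correlation). The list was called lower with a median log2 fold change of -0.33, while the member that passed, Rps2 (2.07 ± 0.33), was higher and is 1 of the position genes (outer against inner -1.35). Among cholesterol synthesis genes, 0 of 21 members were higher and 3 lower (1 and 7 adjusted over the list alone), with the synthase Hmgcs1 (-0.83 ± 0.21) and Acat2 (-1.15 ± 0.33). The cholesterol list had camera adjusted p = 0.0031 (0.54 with an estimated correlation). For macrophage markers, 0 of 15 members were higher and 3 lower (0 and 4 adjusted over the list alone), and the 3 were C1qa, C1qb and the lipoprotein gene Apoe (-1.08 ± 0.25). The macrophage list had camera adjusted p = 0.027 (0.46 with an estimated correlation).

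In all, edgeR called 918 genes in medium, 680 higher and 238 lower in KO cells. The lower count was 108 without KO_medium replicate 1, 136 and 154 without WT_medium replicates 1 and 2, and 157 without KO_medium replicate 4. All WT medium libraries had outer codes and all KO medium libraries inner codes, so no within-position value could be had, and with position as a term 68 genes passed (59 higher, 9 lower, 67 shared with the 918). Of the 27 genes the naming rule took, 11 passed with the term: Pim1, H2-T23, Fam213b, Nptn, Grn, Gm6034, Gm8909, H2-T10, A930015D03Rik, Ide and H2-T9. Pim1 stayed at 3.77, Grn at -1.01 (adjusted p = 0.0024) and H2-T23 at -1.58 (adjusted p = 1.7e-09). The 622 higher calls lost went from a median of 1.08 to 0.55 (median SE 0.25 to 0.27), and the 229 lower calls lost went from a median of -0.61 to -0.46 (median SE 0.17 to 0.21). Cebpb (3.51 ± 0.65, then 1.38 ± 0.65, adjusted p = 0.48) and Rnf187 (3.28 ± 0.56, then 0.77 ± 0.30, adjusted p = 0.32) shrank, log2 fold change ± SE without and with the term. In contrast C1qa (-1.94 ± 0.35, then -1.71 ± 0.45, adjusted p = 0.059), C1qb (-1.51 ± 0.34, then -1.42 ± 0.44, adjusted p = 0.16), Pira2 (-1.46 ± 0.31, then -1.46 ± 0.40, adjusted p = 0.08), Padi4 (-1.26 ± 0.25, then -1.30 ± 0.34, adjusted p = 0.05) and H2-Bl (3.08 ± 0.65, then 3.01 ± 0.80, adjusted p = 0.059) kept most of their size. The largest unadjusted p called was 0.0045 without and 0.00029 with the term, and these 5 genes had at most 0.0028 with it, so both a wider SE and this lower limit bear on their calls. With the term, the list calls for oxidative phosphorylation (camera adjusted p = 0.1), ribosomal proteins (adjusted p = 0.083) and interferon-stimulated genes (adjusted p = 0.28) no longer passed. Those for cytokines (adjusted p = 8.1e-06), NF-kB feedback (adjusted p = 9.4e-05), cholesterol synthesis (adjusted p = 0.00052) and macrophage markers (adjusted p = 0.0072) passed with it. Of the members of these lists named here, Tnfsf15 passed with the term (1.42). Il1b (0.90 ± 0.27, then 1.27 ± 0.33, adjusted p = 0.052), Il1a (0.72 ± 0.22, then 0.88 ± 0.27, adjusted p = 0.16), Il1rn (0.51 ± 0.14, then 0.55 ± 0.17, adjusted p = 0.14), Hmgcs1 (-0.83 ± 0.21, then -1.04 ± 0.27, adjusted p = 0.05) and Apoe (-1.08 ± 0.25, then -1.11 ± 0.32, adjusted p = 0.11) kept or gained size, with an unadjusted p of at most 0.0027 with the term, so the lower limit ended their calls. Nfkbiz (0.80 ± 0.17, then 0.71 ± 0.21, adjusted p = 0.11), Rsad2 (1.03 ± 0.34, then 0.89 ± 0.43, adjusted p = 0.49) and Acat2 (-1.15 ± 0.33, then -0.97 ± 0.41, adjusted p = 0.4) kept most of it, while Tnfaip3 (0.79 ± 0.25, then 0.12 ± 0.26, adjusted p = 0.94), Cmpk2 (1.20 ± 0.36, then 0.72 ± 0.43, adjusted p = 0.63), Cox5b (-0.46 ± 0.12, then -0.34 ± 0.15, adjusted p = 0.4), Ndufa1 (-0.47 ± 0.13, then -0.22 ± 0.15, adjusted p = 0.7) and Rps2 (2.07 ± 0.33, then 0.72 ± 0.19, adjusted p = 0.05) shrank.

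The genotype comparison after LPS asked which genes differed in stimulated cells. Pim1 was 26.3-fold higher in KO cells (log2 fold change 4.71 ± 0.14 SE, 5 libraries per group, adjusted p = 6.6e-32). Other higher genes were Rnf187 (3.36), Ripk2 (2.32), the kinase of NOD receptor signalling, Plbd2 (2.27), a lysosomal phospholipase B-like protein, and Vapa (2.39), an ER contact-site protein. Kctd13 (2.53), Csn2 (2.50), Bloc1s4 (2.32) and Tpst1 (2.29) were also higher (SE at most 0.79, adjusted p at most 0.049). The ribosomal gene Rps27 (5.04 ± 1.04) was higher as well, but near-identical copies in the genome make its count uncertain. Lower in KO cells were Ide (-1.93), the adhesion receptor Vcam1 (-1.52), the prostaglandin E2 receptor Ptger4 (-1.35), the splicing factor Mbnl1 (-1.39) and Gda (-1.42), guanine deaminase. Pira2 (-1.53), Ifitm1 (-1.36), H2-T23 (-1.42) and Dolpp1 (-1.21) were lower too (SE at most 0.45, adjusted p at most 0.034), as was H2-M2 (-1.72 ± 0.36), whose close MHC class I relatives make it uncertain.

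Of the metallothionein list with LPS, 2 of 3 members were higher and 0 lower (2 and 0 adjusted over the list alone), namely the metal-binding genes Mt1 (0.71 ± 0.13) and Mt2 (0.77 ± 0.13). The metallothionein list had camera adjusted p = 0.00022 (adjusted p = 0.078 with an estimated correlation). For lysosomal genes, 3 of 24 members were higher and 0 lower (3 and 0 adjusted over the list alone), with Lamp1 (1.90 ± 0.31), a position gene (outer against inner -1.27) that was 0.79 with position as a term (adjusted p = 0.018). The lysosomal list had camera adjusted p = 0.038 (adjusted p = 0.72 with an estimated correlation). Among genes that respond to histone deacetylase inhibitors, 1 of 7 members were higher and 0 lower (4 and 0 adjusted over the list alone), the linker histone H1f0 (1.77 ± 0.34). The deacetylase list had camera adjusted p = 0.028 (adjusted p = 0.34 with an estimated correlation). For dendritic cell maturation, 0 of 19 members were higher and 1 lower (0 and 1 adjusted over the list alone), with Marcks (-1.25 ± 0.30). The maturation list had camera adjusted p = 0.021 (adjusted p = 0.71 with an estimated correlation). Il10 (-3.42 ± 0.89), an anti-inflammatory cytokine, was lower in KO cells, and -3.74 ± 1.08 with position as a term (adjusted p = 0.071). In total 623 genes passed, 443 higher and 180 lower (119 lower without WT_LPS replicate 1). Outer codes held every WT and 1 of 5 KO libraries, so no within-position value could be had, and 161 genes passed with position as a term (104 higher, 57 lower, 137 shared). With it 18 of the 26 named genes passed, including Ripk2 (1.22, adjusted p = 0.013), Plbd2 (1.06) and Vapa (0.91), all smaller, but not Rnf187, Kctd13, Csn2, Bloc1s4, Tpst1, H2-M2, Ifitm1 and Ptger4. The 354 higher calls lost went from a median of 1.13 to 0.57 (median SE 0.27 to 0.26), and the 132 lower calls lost went from a median of -0.75 to -0.69 (median SE 0.21 to 0.24). Rnf187 (3.36 ± 0.65, then 1.07 ± 0.33, adjusted p = 0.098), Kctd13 (2.53 ± 0.51, then 0.86 ± 0.33, adjusted p = 0.19), Csn2 (2.50 ± 0.79, then 1.20 ± 0.90, adjusted p = 0.6), Bloc1s4 (2.32 ± 0.56, then 0.65 ± 0.55, adjusted p = 0.65) and Tpst1 (2.29 ± 0.47, then 0.89 ± 0.40, adjusted p = 0.31) shrank, log2 fold change ± SE without and with the term. Ptger4 (-1.35 ± 0.36, then -1.45 ± 0.42, adjusted p = 0.063), Ifitm1 (-1.36 ± 0.33, then -1.21 ± 0.38, adjusted p = 0.1) and H2-M2 (-1.72 ± 0.36, then -1.34 ± 0.40, adjusted p = 0.086) kept most of their size with a wider SE and an unadjusted p of at most 0.0028, where the largest called was 0.003 without and 0.00078 with the term. Of the list members named here H1f0 (1.77 ± 0.34, then 0.83 ± 0.26, adjusted p = 0.097) and Marcks (-1.25 ± 0.30, then -0.92 ± 0.32, adjusted p = 0.16) did not pass either. The list calls for dendritic cell maturation (adjusted p = 0.093) and histone deacetylase response (adjusted p = 0.068) were lost with the term.

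With 4µ8C, the genotype comparison asked the same under an inhibitor of IRE1. Pim1 was 17.2-fold higher in KO cells (log2 fold change 4.11 ± 0.14 SE, 5 libraries per group, adjusted p = 2e-29). Also higher were Tnfsf4 (1.46), the ligand of OX40, Glo1 (1.30), which detoxifies methylglyoxal, the inflammasome sensor Nlrp1a (1.17), the scavenger receptor Colec12 (1.06) and Phlda1 (0.99) (SE at most 0.38, adjusted p at most 0.05 as rounded). Lower were Gal (-1.38), the neuropeptide galanin, Apoe (-1.30), Selm (-1.29), an ER selenoprotein, Grn (-1.18) and H2-T23 (-1.28). Pira2 (-1.27), Gda (-1.11), Chpt1 (-1.03), Flot1 (-1.01) and Ide (-1.04) were lower too, Chpt1 being a phosphatidylcholine synthesis enzyme and Flot1 a lipid raft protein (SE at most 0.32, adjusted p at most 0.046). Of oxidative phosphorylation genes, 0 of 23 members were higher and 2 lower (0 and 8 adjusted over the list alone), as for Cox5b (-0.51 ± 0.12) and Sdhb (-0.52 ± 0.12). The oxidative phosphorylation list had camera adjusted p = 1.5e-05 (adjusted p = 0.41 with an estimated correlation). For cytosolic ribosomal proteins, 0 of 32 members were higher and 0 lower (0 and 0 adjusted over the list alone), with a median of -0.27. The ribosomal protein list had camera adjusted p = 1.6e-05 (adjusted p = 0.76 with an estimated correlation). For monocyte markers, 0 of 8 members were higher and 0 lower (0 and 3 adjusted over the list alone), with a median of -0.35. The monocyte list had camera adjusted p = 0.002 (adjusted p = 0.058 with an estimated correlation). For ER chaperones and ATF6 targets, 1 of 18 members were higher and 0 lower (2 and 0 adjusted over the list alone), the disulfide isomerase P4hb (0.42 ± 0.11). The ATF6 list had camera adjusted p = 0.037 (adjusted p = 0.41 with an estimated correlation).

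The count in 4µ8C was 98 genes, 44 higher and 54 lower in KO cells, and 111 with position as a term, with which all 23 named genes passed. It was 19 in a fit of these 10 libraries alone, 175 with replicate as a block and 167 by DESeq2. Within inner positions (3 libraries per group) 96 genes passed (36 higher, 60 lower, 47 among the 98), and within outer positions (2 per group) 28 (21 higher, 7 lower, 7 among the 98). Leaving out 1 library gave between 42 (without WT_4u8C replicate 3) and 124 genes, and 21 and 28 higher ones without WT_4u8C replicate 1 and KO_4u8C replicate 3.

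With 4PBA the genotype comparison asked the same in cells given a chemical chaperone. Pim1 was 13.5-fold higher in KO cells (log2 fold change 3.75 ± 0.14 SE, 5 libraries per group, adjusted p = 2.3e-28). Higher genes further included Glo1 (1.03), Hbegf (0.98), an EGF-family growth factor, the mitochondrial proteins C1qbp (0.94) and Hspa9 (0.65), and the prolyl peptidase Prep (0.94) (SE at most 0.24, adjusted p at most 0.038). Lower were Tmem160 (-1.47), Camk1 (-1.38), a calmodulin-dependent kinase, Gstt1 (-1.21), a glutathione transferase, Apoe (-1.20) and Selm (-1.26). Pira2 (-1.45), Ifitm1 (-1.39), Ide (-1.17) and H2-T23 (-1.15) were lower too (SE at most 0.34, adjusted p at most 0.045). Of monocyte markers, 0 of 8 members were higher and 0 lower (0 and 2 adjusted over the list alone), with a median of -0.35. The monocyte list had camera adjusted p = 0.00086 (adjusted p = 0.036 with an estimated correlation). For cytosolic ribosomal proteins, 0 of 32 members were higher and 0 lower (0 and 0 adjusted over the list alone), with a median of -0.33. The ribosomal protein list had camera adjusted p = 1.1e-08 (adjusted p = 0.64 with an estimated correlation). For cholesterol synthesis, 0 of 21 members were higher and 1 lower (0 and 1 adjusted over the list alone), the 1 being Hmgcs1 (-0.96 ± 0.21). The cholesterol list had camera adjusted p = 0.00019 (adjusted p = 0.41 with an estimated correlation). For plasmacytoid dendritic cell markers, 0 of 4 members were higher and 0 lower (0 and 1 adjusted over the list alone), and with position as a term the call was lost (adjusted p = 0.051). The plasmacytoid list had camera adjusted p = 0.04 (adjusted p = 0.27 with an estimated correlation).

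With 4PBA 51 genes passed, 19 higher and 32 lower in KO cells. All 10 libraries had inner codes (WT in row C, KO in row G). Position as a term gave 148 genes (51 shared), inner libraries alone 173, these 10 alone 198, replicate as a block 115 and DESeq2 83. Leaving out 1 library gave between 22 (without KO_4PBA replicate 4) and 61 genes.

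Across the 4 genotype comparisons, 17 genes passed in the same direction each time, 8 higher and 9 lower in KO cells. By mean log2 fold change over the 4 comparisons, Pim1 (4.11) and Glo1 (1.04) were higher, and Pira2 (-1.43), H2-T23 (-1.39), Ide (-1.31), Grn (-1.11), Gda (-1.04), Tgfbi (-0.81), Flot1 (-0.78) and Serinc3 (-0.73) were lower. Tgfbi encodes an extracellular matrix protein induced by TGF-beta and Serinc3 a membrane protein that restricts retroviruses. The MHC class I relatives Gm6034 (3.69), H2-Bl (3.51), Gm8909 (2.08), H2-T10 (1.70) and H2-T9 (-1.15) were in the set, and their counts are uncertain because reads can fit several copies. The other 2 were unnamed transcripts. Glo1, Grn, Gda, Tgfbi, Flot1 and Serinc3 lay outside the 10 with the largest mean change and are named here after their values were seen. In the mouse assembly GRCm38.p6, 10 of the 16 genes with a known chromosome lay on chromosome 17, which also holds Bag6, against 0.87 expected from the tested genes. Chromosome 17 held 6.3% of the genes called in medium, 6.3% with LPS, 12.4% with 4µ8C (Fisher's exact test, two-sided, adjusted p = 0.012) and 24.5% with 4PBA (adjusted p = 3.4e-05), against 5.4% of the tested genes with a chromosome.

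LPS against medium asked how stimulation acted on each genotype. In WT cells Il33 (6.81), an alarmin cytokine (log2 fold change, 5 libraries per group), Vcam1 (5.98), Il6 (4.78) and Ptgs2 (4.62), the inducible cyclooxygenase, rose most among named genes. Il1a (3.98), Il1b (3.94) and the protease inhibitor Serpinb1a (3.91) rose too (SE at most 1.15, adjusted p at most 1.1e-05). In KO cells Csf3 (4.80), which encodes G-CSF, Hamp (4.18), the iron hormone hepcidin, and Ptgs2 (4.09), Il6 (3.81), Il27 (3.66) and Il1b (3.57) rose (SE at most 0.98, adjusted p at most 0.00029). In WT cells the receptor Cd300lb (-4.22), the glycosyltransferase Gcnt1 (-3.49), the adhesion receptor Cd97 (-3.10) and Idh1 (-3.23), the cytosolic isocitrate dehydrogenase, fell (SE at most 0.45, adjusted p at most 2.2e-08). In KO cells Cd200r1 (-3.17), an inhibitory receptor, Cnr2 (-3.00), a cannabinoid receptor, and Gcnt1 (-3.05), Idh1 (-2.91) and Cd300lb (-2.89) fell (SE at most 0.44, adjusted p at most 2.2e-07).

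Members of the inflammatory cytokine list with LPS were 19 higher and 0 lower in WT and 17 and 0 in KO cells of 19 tested (19 and 0, then 19 and 0, adjusted over the list alone), for example Tnf (2.60 ± 0.36 and 2.09 ± 0.35) in WT and KO cells. The cytokine list had camera adjusted p = 9.3e-19 in WT and 1.1e-18 in KO cells (adjusted p = 0.00053 and 0.00056 with an estimated correlation). NF-kB feedback genes were 20 higher and 0 lower in WT and 19 and 0 in KO cells of 20 tested (20 and 0, then 19 and 0, adjusted over the list alone), with Nfkbiz (2.76 ± 0.17 and 2.28 ± 0.16). The NF-kB feedback list had camera adjusted p = 8.9e-31 in WT and 3.6e-31 in KO cells (adjusted p = 0.0003 and 0.0003 with an estimated correlation). Interferon-stimulated genes were 24 higher and 0 lower in WT and 24 and 0 in KO cells of 24 tested (24 and 0, then 24 and 0, adjusted over the list alone), with Gbp5 (3.23 ± 0.23 and 2.73 ± 0.22), a guanylate-binding GTPase. The interferon list had camera adjusted p = 3.6e-19 in WT and 1.2e-16 in KO cells (adjusted p = 0.2 and 0.27 with an estimated correlation). Dendritic cell maturation genes were 15 higher and 0 lower in WT and 9 and 0 in KO cells of 19 tested (16 and 0, then 9 and 0, adjusted over the list alone), with the costimulatory receptor Cd40 (3.22 ± 0.27 and 2.61 ± 0.27). The maturation list had camera adjusted p = 1e-07 in WT and 0.00032 in KO cells (adjusted p = 0.25 and 0.5 with an estimated correlation). Early genes of stress and cell handling were 6 higher and 5 lower in WT and 6 and 2 in KO cells of 14 tested (7 and 5, then 6 and 2, adjusted over the list alone). The early gene list had camera adjusted p = 0.13 in WT and 0.0049 in KO cells (adjusted p = 0.82 and 0.54 with an estimated correlation). They were called in KO cells alone, but the test of the difference between genotypes gave camera adjusted p = 0.1 (adjusted p = 0.79 with an estimated correlation).

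With LPS 4123 genes passed in WT cells, 1932 higher and 2191 lower, and 3618 in KO cells, 1718 and 1900. The WT response within outer positions gave 3837 genes and the KO response within inner positions 3612. Same-numbered KO libraries paired between the groups, and the KO count blocked by replicate within genotype was 4030. The LPS responses of both genotypes, estimated from separate libraries, correlated across the 10287 genes with Pearson's r = 0.82 and Spearman's rho = 0.80, as 1 of 10 such pairs computed, where genes are not independent replicates.

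**Figure D3:**
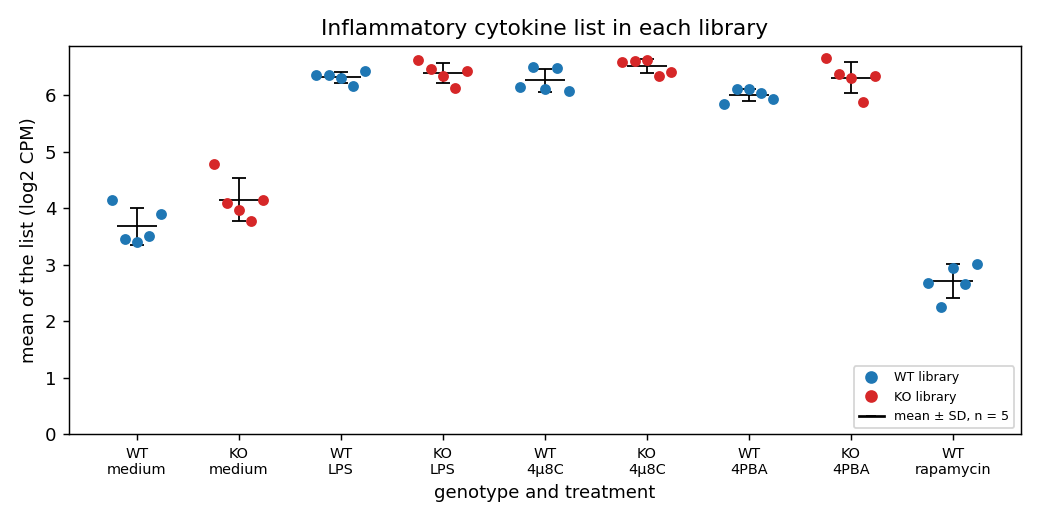
Mean log2 CPM of the inflammatory cytokine list in each library, with mean and SD of 5 libraries as bars. WT medium libraries lay between 3.41 and 4.14, and KO medium libraries between 3.77 and 4.79. Rapamycin libraries lay between 2.25 and 3.02, and all LPS, 4µ8C and 4PBA libraries between 5.85 and 6.65.

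4µ8C against medium asked what an IRE1 inhibitor did in each genotype. In WT cells Il33 (6.77), Vcam1 (6.05), Il6 (4.51), Ptgs2 (4.32) and Il1b (4.08) rose (log2 fold change, 5 libraries per group), and so did Hamp (3.85), Vcam1 (3.85), Ptgs2 (3.70), Il6 (3.70) and Il1b (3.37) in KO cells (SE at most 1.17, adjusted p at most 1.3e-05). Cd300lb (-4.05), Idh1 (-3.57), Gcnt1 (-3.31) and the fatty acid desaturase Fads1 (-3.09) fell in WT cells. In KO cells Phlda3 (-3.48), Idh1 (-2.89), Cd300lb (-2.65), Cd200r1 (-2.54) and Nt5e (-2.63), the ectonucleotidase CD73, fell (SE at most 0.53, adjusted p at most 9.8e-07). The cytokine list was 19 higher and 0 lower in WT and 19 and 0 in KO cells of 19 tested (19 and 0, then 19 and 0, adjusted over the list alone), with Tnf (2.41 ± 0.36 and 2.31 ± 0.36). The cytokine list had camera adjusted p = 1.2e-18 in WT and 5.2e-20 in KO cells (adjusted p = 0.00056 and 0.00041 with an estimated correlation). NF-kB feedback genes were 20 higher and 0 lower in WT and 20 and 0 in KO cells of 20 tested (20 and 0, then 20 and 0, adjusted over the list alone). The NF-kB feedback list had camera adjusted p = 6.5e-29 in WT and 9.8e-31 in KO cells (adjusted p = 0.00033 and 0.0003 with an estimated correlation). The early gene list was 6 higher and 3 lower in WT and 6 and 2 in KO cells of 14 tested (6 and 3, then 6 and 2, adjusted over the list alone), and the test of the difference between genotypes gave camera adjusted p = 0.4 (adjusted p = 0.92 with an estimated correlation). The early gene list had camera adjusted p = 0.077 in WT and 0.0038 in KO cells (adjusted p = 0.76 and 0.53 with an estimated correlation).

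With 4µ8C 4122 genes passed in WT cells (2059 higher, 2063 lower) and 3360 in KO cells (1657 higher, 1703 lower). Outer positions alone (5 WT medium and 2 WT 4µ8C libraries) gave 2222 genes, inner positions alone (5 KO medium and 3 KO 4µ8C libraries) gave 2825, and the KO count blocked within genotype was 3743. The WT 4µ8C response and the KO LPS response, which share no library, correlated across genes with r = 0.80 and rho = 0.78 (1 of 10 pairs computed, genes not being independent replicates). Of the genes called in both, 1387 were higher in both against 344 expected by chance, 1308 lower in both against 381, and 4 opposite.

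4µ8C against LPS, a comparison added after the data were seen, set the inhibitor groups beside the stimulated ones. In WT cells 21 genes were higher with 4µ8C and 0 lower, 783 genes having an unadjusted p under 0.05 in edgeR. They included Cdc16 (1.90), Plbd2 (1.72), Mrs2 (1.55) and E2f5 (1.11) (log2 fold change, 5 libraries per group), Cdc16 being a subunit of the anaphase-promoting complex and E2f5 a cell cycle repressor, and Ddit4 (0.72), an inhibitor of mTORC1 (SE at most 0.38, adjusted p at most 0.046). With position as a term 0 genes passed in edgeR, the 21 higher calls lost went from a median of 1.09 to 0.56 (median SE 0.24 to 0.17), and 0 passed within outer positions, while DESeq2 without the term called 68. Leaving out 1 library gave from 1 (without WT_LPS replicate 2) to 57 (without WT_4u8C replicate 4). In KO cells 3 genes were lower with 4µ8C, namely Ddit4 (-0.83), Brwd1 (-0.93), a bromodomain protein, and Gramd1a (-1.02), a cholesterol transporter of the ER, the last named after its value was seen (SE at most 0.21, adjusted p at most 0.04). Same-numbered KO libraries paired, and blocking within genotype gave 13 genes, inner positions alone 12, and a fit of the 10 libraries alone 0 in edgeR, where DESeq2 on all libraries called 10. The IRE1-XBP1 target list, ER genes induced by the product of IRE1's RNase, was called lower with 4µ8C in both genotypes, with median log2 fold changes of -0.16 in WT and -0.14 in KO cells. Its members were 0 higher and 0 lower in WT and 0 and 0 in KO cells of 20 tested (0 and 0, then 0 and 0, adjusted over the list alone), and the WT call was lost with position as a term (adjusted p = 0.11). The XBP1 list had camera adjusted p = 0.0025 in WT and 0.016 in KO cells (adjusted p = 0.24 and 0.39 with an estimated correlation).

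4PBA against medium asked how the groups labelled 4PBA differed from medium in each genotype, again with LPS not stated to be absent. In WT cells Il33 (5.99) (log2 fold change, 5 libraries per group), Stbd1 (5.35), a glycogen-binding protein, Ptgs2 (4.78), Abhd6 (4.42), a monoacylglycerol lipase, and Lipg (4.31), endothelial lipase, rose. In KO cells Il6 (4.45), Hamp (4.27), Ptgs2 (4.08), Abhd6 (3.91) and Hdc (3.23), histidine decarboxylase, rose (SE at most 1.21, adjusted p at most 0.00012). Idh1 (-3.28), Cd300lb (-3.21), Lair1 (-2.57) and the scavenger receptor Stab1 (-2.69) fell in WT cells. In KO cells Phlda3 (-3.64), Idh1 (-2.50), Stab1 (-2.29) and Gclm (-2.75), a subunit of the glutathione synthesis enzyme, fell (SE at most 0.54, adjusted p at most 1.4e-06). The cytokine list was 16 higher and 0 lower in WT and 16 and 0 in KO cells of 19 tested (18 and 0, then 18 and 0, adjusted over the list alone). The cytokine list had camera adjusted p = 1.5e-14 in WT and 2.8e-17 in KO cells (adjusted p = 0.0031 and 0.0011 with an estimated correlation). NF-kB feedback genes were 18 higher and 0 lower in WT and 17 and 0 in KO cells of 20 tested (19 and 0, then 18 and 0, adjusted over the list alone). The NF-kB feedback list had camera adjusted p = 8e-18 in WT and 2.7e-17 in KO cells (adjusted p = 0.0063 and 0.0063 with an estimated correlation).

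With 4PBA 4495 genes passed in WT cells (2303 higher, 2192 lower) and 3413 in KO cells (1750 and 1663). WT medium and WT 4PBA held 1 kind of position each, so no within-position value could be had, and 2790 genes passed with position as a term (2651 shared). All KO libraries of this comparison had inner codes, and a fit of inner libraries gave 3823 genes. Same-numbered libraries paired in both genotypes, and blocking within genotype gave 4923 genes in WT and 3869 in KO cells, with the KO ribosomal protein list then called lower (camera adjusted p = 0.07 without and 0.02 with replicate as a block, adjusted p = 0.94 with an estimated correlation and no block). The WT 4PBA response correlated with the KO LPS response across genes at r = 0.57 and rho = 0.52 (1 of 10 pairs computed, genes not being independent replicates).

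4PBA against LPS was also added after the data were seen. Abhd6 (3.91 ± 0.40 and 3.24 ± 0.36) was higher with 4PBA in WT and KO cells (log2 fold change, 5 libraries per group). Lower in both were Lox (-3.10 ± 0.48 and -2.11 ± 0.42), Marco (-2.43 ± 0.32 and -1.80 ± 0.30) and Ptpn1 (-1.94 ± 0.19 and -1.86 ± 0.19), Lox being lysyl oxidase, Marco a scavenger receptor and Ptpn1 a tyrosine phosphatase (SE at most 0.48, adjusted p at most 0.00019). In WT cells Stbd1 (4.10), Rnf187 (3.85), Cebpb (3.84) and Camk1 (3.39) were higher and the chemokine Ccl7 (-2.13), the clock gene Per2 (-2.03) and the protease Ctsk (-1.93) lower (SE at most 0.72, adjusted p at most 0.00099). In KO cells Trove2 (3.06), Pfn2 (2.87) and Il16 (2.57) were higher and Il1f6 (-1.67) and Nr1h3 (-1.71), the oxysterol receptor LXR-alpha, lower (SE at most 0.40, adjusted p at most 0.00013). Glycolysis genes were 0 higher and 18 lower in WT and 0 and 17 in KO cells of 20 tested (0 and 18, then 0 and 17, adjusted over the list alone), with Hk2 (-0.97 ± 0.14 and -0.75 ± 0.14) and Ldha (-0.71 ± 0.12 and -0.81 ± 0.12). The glycolysis list had camera adjusted p = 2.6e-12 in WT and 1.6e-15 in KO cells (adjusted p = 0.074 and 0.032 with an estimated correlation). NF-kB feedback genes were 0 higher and 9 lower in WT and 0 and 8 in KO cells of 20 tested (0 and 11, then 0 and 9, adjusted over the list alone), and the cytokine Tnf (-1.76 ± 0.35 and -1.23 ± 0.34) was lower. The NF-kB feedback list had camera adjusted p = 0.0022 in WT and 1.5e-05 in KO cells (adjusted p = 0.54 and 0.34 with an estimated correlation). Monocyte markers were called lower with 4PBA in KO cells, where 0 of 8 members were higher and 5 lower (0 and 5 adjusted over the list alone). The monocyte list had camera adjusted p = 0.0049 (adjusted p = 0.084 with an estimated correlation).

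For 4PBA against LPS 2781 genes passed in WT cells (1543 higher, 1238 lower) and 2507 in KO cells (1326 and 1181). WT LPS had only outer and WT 4PBA only inner codes, and with position as a term 1526 genes passed in WT cells (1354 shared). Lost calls included Stbd1 (4.10 ± 0.72, then 2.62 ± 0.97, adjusted p = 0.059), Cebpb (3.84 ± 0.71, then 1.70 ± 0.70, adjusted p = 0.1) and Ccl7 (-2.13 ± 0.48, then -1.61 ± 0.60, adjusted p = 0.065), each smaller with the term. Rnf187 (1.34) and Camk1 (2.15) passed with it, also over 1.5 times smaller. Inner positions gave 2731 in KO cells, and blocking within genotype gave 3204 in WT and 2996 in KO cells, with KO macrophage markers then called lower (camera adjusted p = 0.053 without and 0.045 with replicate as a block, adjusted p = 0.54 with an estimated correlation and no block).

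Rapamycin against medium asked what inhibition of mTORC1 did in WT cells. The chemokines Ccl7 (-3.95), Ccl2 (-3.30) and Cxcl10 (-2.85) fell (log2 fold change, 5 libraries per group), as did the nitric oxide synthase Nos2 (-3.29), the AP-1 factor Fosl1 (-3.91) and the pattern recognition molecule Ptx3 (-2.53). Hdc (-3.22), Adm (-3.02) and Ifit2 (-2.70) fell too (SE at most 0.62, adjusted p at most 6.5e-06). Eif3f (2.56), a translation initiation factor subunit, Uck2 (2.56), Arrdc4 (2.41) and Pdf (2.31), a peptide deformylase, rose. Rnf187 (3.01), Scand1 (2.35), Thap11 (2.21), Atad3a (2.21) and Xpa (2.20) rose too (SE at most 0.55, adjusted p at most 0.00026). Of interferon-stimulated genes, 0 of 24 members were higher and 24 lower (0 and 24 adjusted over the list alone), as for Isg15 (-2.51 ± 0.26) and Oasl1 (-2.45 ± 0.21). The interferon list had camera adjusted p = 2e-32 (adjusted p = 0.038 with an estimated correlation). For glycolysis, 0 of 20 members were higher and 18 lower (0 and 19 adjusted over the list alone), with the glucose transporter Slc2a1 (-1.76 ± 0.15) and Hk2 (-1.37 ± 0.15). The glycolysis list had camera adjusted p = 8.6e-19 (adjusted p = 0.015 with an estimated correlation).

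For cytosolic ribosomal proteins with rapamycin, 25 of 32 members were higher and 0 lower (29 and 0 adjusted over the list alone), as for Rpl3 (0.91 ± 0.31) and Rpl6 (0.85 ± 0.19). The ribosomal protein list had camera adjusted p = 3.8e-10 (adjusted p = 0.57 with an estimated correlation). For autophagy, 9 of 20 members were higher and 0 lower (10 and 1 adjusted over the list alone), with Map1lc3a (1.98 ± 0.31). The autophagy list had camera adjusted p = 0.0012 (adjusted p = 0.1 with an estimated correlation). Camera called no cell marker list with rapamycin, though fry passed plasmacytoid (adjusted p = 2.2e-06), macrophage (adjusted p = 0.0071) and monocyte markers (adjusted p = 0.0054). Of plasmacytoid markers 2 of 4 were lower (camera adjusted p = 0.06, 0.045 with replicate as a block), and of macrophage markers 1 higher and 6 lower of 15 (camera adjusted p = 0.21). In all 2388 genes passed, 996 higher and 1392 lower, against 1209 and 1191 in a fit of these 10 libraries alone. Outer positions alone (5 medium and 2 rapamycin libraries) gave 1142 genes, and 1810026J23Rik was the named gene that did not pass with position as a term. Over 1.5 times smaller with the term were Rnf187 (1.06), Uck2 (1.21), Scand1 (1.22), Arrdc4 (1.35), Thap11 (1.36), Eif3f (1.67) and Map1lc3a (1.23). The labels name no vehicle group for rapamycin or for the other compounds.

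Differences between the genotypes in each response were tested as interactions, (KO treated minus KO medium) minus (WT treated minus WT medium). For LPS 1 gene passed in edgeR (758 had an unadjusted p under 0.05 and DESeq2 called 3), Ccdc50 (-0.91 ± 0.15), an adaptor of NF-kB signalling (log2 difference ± SE, 5 libraries in each of 4 groups, adjusted p = 0.0018). Blocking within genotype raised the count to 28, and fitting the 20 libraries alone gave 0. For 4µ8C 184 genes passed, 175 with a lower response in KO cells. These included Syap1 (-3.39), Ndnl2 (-3.10), Rnf187 (-3.04), Marcksl1 (-2.98), Uck2 (-2.84) and Adssl1 (-2.91), a purine synthesis enzyme. In contrast Cd300lb (1.40), Gtf3a (1.19), Gnl3l (1.19), Acox3 (0.81) and Stt3a (0.64) had a higher response (SE at most 0.77, adjusted p at most 0.045). With position as a term the 175 lower calls lost went from a median of -1.58 to -0.72 (median SE 0.37 to 0.31), as for Syap1 (-3.39 ± 0.70, then -1.55 ± 0.58, adjusted p = 0.67) and Rnf187 (-3.04 ± 0.77, then -0.54 ± 0.39, adjusted p = 0.87). Cd300lb (1.40 ± 0.31, then 1.47 ± 0.36, adjusted p = 0.27), Gnl3l (1.19 ± 0.33, then 1.18 ± 0.38, adjusted p = 0.59), Acox3 (0.81 ± 0.22, then 0.82 ± 0.25, adjusted p = 0.55), Stt3a (0.64 ± 0.16, then 0.64 ± 0.18, adjusted p = 0.4) and Gtf3a (1.19 ± 0.33, then 1.00 ± 0.37, adjusted p = 0.66) kept most of their size with a wider SE, Cd300lb and Stt3a within the 0.00088 that was the largest unadjusted p called without the term. In all 0 passed in edgeR for 4µ8C with the term, where DESeq2 without the term called 250 and 1066 had an unadjusted p under 0.05 in edgeR without the term.

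For 4PBA 487 genes passed the interaction test, 32 higher and 455 lower in KO cells, and 126 with position as a term. Lower responses were seen for Cebpb (-5.36), Phlda3 (-4.81) and Fst (-4.73), the activin antagonist follistatin (log2 difference, 5 libraries in each of 4 groups), and Ndnl2 (-4.71), Syap1 (-4.54) and Rnf187 (-4.52). Higher ones were seen for Marco (1.57), Cxcr2 (1.41), Nptn (1.34), Cd300lb (1.15), Ddx27 (1.16) and Lcmt2 (1.12) (SE at most 0.86, adjusted p at most 0.026). With the term Cd300lb (1.22), Fst (-3.85), Cebpb (-3.23), Ndnl2 (-3.00), Syap1 (-2.83) and Rnf187 (-2.01) passed (adjusted p at most 0.03), the last 4 being over 1.5 times smaller. The 332 lower calls lost went from a median of -1.57 to -0.88 (median SE 0.37 to 0.37), as for Phlda3 (-4.81 ± 0.77, then -2.95 ± 0.90, adjusted p = 0.1). Calls ended too for Cxcr2 (1.41 ± 0.30, then 0.93 ± 0.30, adjusted p = 0.16) and Lcmt2 (1.12 ± 0.28, then 0.67 ± 0.29, adjusted p = 0.52), which shrank, and for Marco (1.57 ± 0.44, then 1.26 ± 0.49, adjusted p = 0.39), Nptn (1.34 ± 0.37, then 1.51 ± 0.42, adjusted p = 0.067) and Ddx27 (1.16 ± 0.33, then 1.05 ± 0.38, adjusted p = 0.27), which kept most of their size. Of the fixed lists, the LPS interaction was called higher for ribosomal proteins, where 0 of 32 members were higher and 0 lower (1 and 0 adjusted over the list alone). The ribosomal protein list had camera adjusted p = 5.6e-09 (adjusted p = 0.63 with an estimated correlation). The LPS interaction was called lower for dendritic cell maturation, where 0 of 19 members were higher and 0 lower (0 and 0 adjusted over the list alone). The maturation list had camera adjusted p = 0.00013 (adjusted p = 0.46 with an estimated correlation). Macrophage markers were called higher, though 0 of 15 members were higher and 0 lower (0 and 0 adjusted over the list alone). The macrophage list had camera adjusted p = 0.002 (adjusted p = 0.3 with an estimated correlation). For 4PBA, NF-kB feedback genes were called lower, and 0 of 20 members were higher and 1 lower (0 and 1 adjusted over the list alone). The feedback gene list had camera adjusted p = 0.025 (adjusted p = 0.68 with an estimated correlation). Oxidative phosphorylation was called higher for 4PBA, where 0 of 23 members were higher and 0 lower (0 and 0 adjusted over the list alone), and this call was lost with position as a term (adjusted p = 0.74). The oxidative phosphorylation list had camera adjusted p = 0.023 (adjusted p = 0.75 with an estimated correlation).

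**Figure D4:**
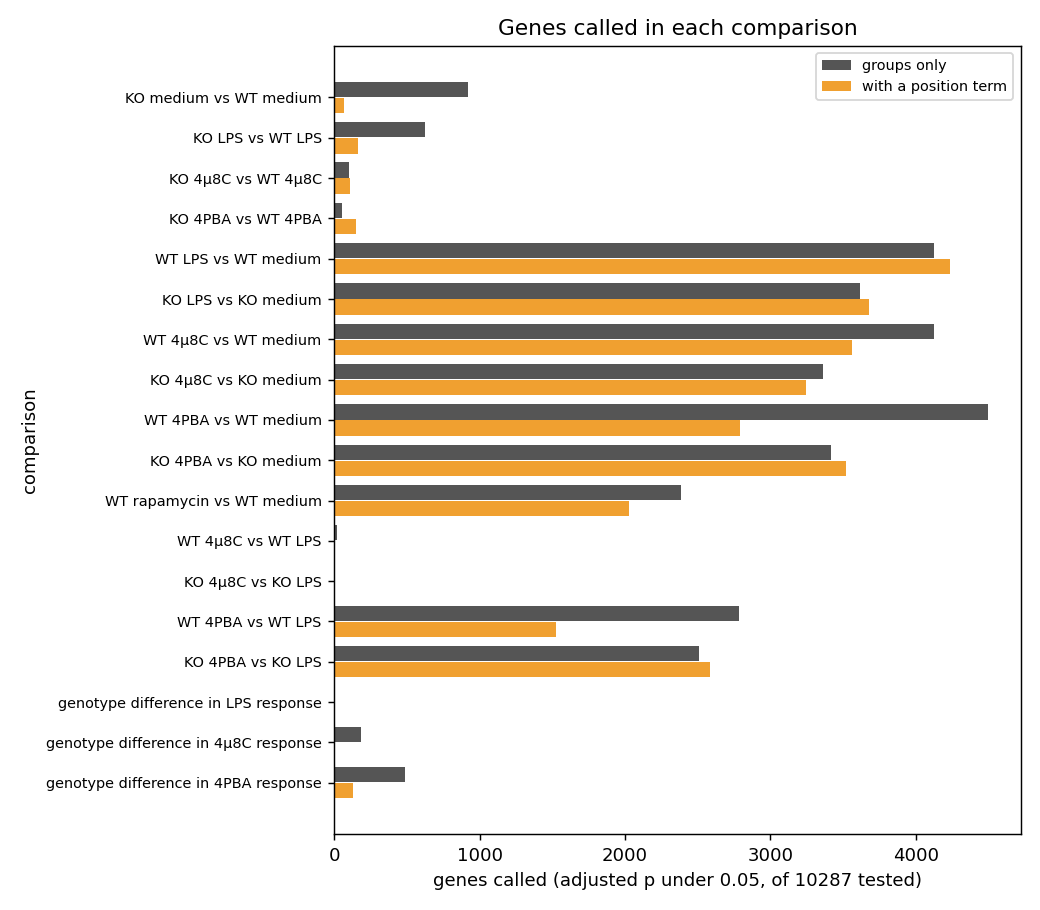
Genes called by edgeR (adjusted p under 0.05, of 10287 tested) in each of 18 comparisons, from a fit of the groups only and from a fit with outer or inner position as a term. In medium the genotype count was 918 without and 68 with the term, and with 4PBA 51 and 148.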

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

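The tests of plate position, of a larger effect without treatment, of the LPS response in inhibitor groups and of gene order near Bag6 were chosen only after the result was seen. So were the splits of KO medium with WT medium, of KO LPS with WT LPS and of the LPS interaction, and those that part every pair, while the depth test and the other splits were chosen before.

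Of 162 groups of 5 libraries tested for a library far from the rest, 12 held one, and chance gives about 1 in 20, or 8.1. Bag6 stood at 12.4 CPM in KO_4PBA replicate 4, against 4.85 to 7.01 in the other 4 libraries, and the same library had 13567 genes above 0 against 12879 to 13048. Rnf187 stood at 9.86 CPM in KO_LPS replicate 5 against 74.8 to 97.8, the 1 outer library of that group, and at 70.3 in WT_4PBA replicate 1 against 96.4 to 104. H2-T23 was 709 CPM in WT_medium replicate 1 (others 427 to 505), and C1qa 14.2 in WT_4u8C replicate 5 (31.5 to 36.7). Abhd6 was 3.33 CPM in WT_4u8C replicate 2 (1.46 to 1.86) and 0.605 in KO_medium replicate 3 (1.25 to 1.49). Nos2 was 2633 CPM in WT_4PBA replicate 4 (2288 to 2360) and 135 in WT_rapamycin replicate 5 (59.6 to 70.4). WT_4u8C replicate 4 had a TMM factor of 0.717 (0.883 to 0.937) and 12.1% of its counts in Rn45s (10.2 to 10.7).

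The interaction test called 1 gene with LPS, 184 with 4µ8C and 487 with 4PBA. All WT medium libraries were outer and all KO medium libraries inner, and with position as a term the counts were 1, 0 and 126 in edgeR, so for 4µ8C and 4PBA a genotype effect on the response is not separated from position. With LPS position nearly cancels, since the WT LPS libraries were outer too and 4 of 5 KO LPS libraries inner, and Ccdc50 stayed at -0.93 (adjusted p = 0.0012) with the term. Of the 4PBA genes with an estimate, 13 of 474 (2.7%) had the sign of the inner-minus-outer difference, against 36.6% of all genes, and the opposite sign is what the medium groups' positions predict. Chance could not be excluded for LPS. The 20 libraries alone called 0 genes in edgeR, so 100 of 100 splits drawn had to call as many, up to 237, and the split test says nothing about Ccdc50. For 4µ8C 3 of 100 splits, the real one included, called as many as the real 152, a narrow margin against chance. Since 1 called 477, a sign of structure other than the labels, chance was not firmly excluded. For 4PBA 1 of 100, the real one, called as many as 573, against at most 27 in another split, so chance was excluded, while position was not.

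First, more genes differed by genotype in medium (918) than with 4PBA (51). Sequencing depth was excluded, since the ratio of the counts was 14.5 with all libraries thinned to the lowest total and 18 before. Outer plate position may account for much of the medium count. In the 4 groups that held both kinds of position, the inner-minus-outer difference had the sign of KO minus WT for 89.2% of called genes (794 of 890), against 65% of all genes, and for 44.9% of those called with 4PBA. A larger genotype effect without treatment stays open, because genotype and position coincide in medium. With position as a term medium gave 68 genes and 4PBA 148, but the median SE widened from 0.22 to 0.27 in medium and stayed at 0.22 with 4PBA.

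Second, the 4µ8C and 4PBA groups carried much of the LPS response. Handling common to all added compounds stays open, since rapamycin's own action can mask it (WT rapamycin with KO LPS response, r = -0.39). Single mislabelled libraries were excluded, as 20 of 20 inhibitor libraries lay above every medium library in the mean of the cytokine list. LPS in the 4µ8C and 4PBA cultures may explain the pattern and stays open. With the other genotype's LPS response, r was 0.80 (WT) and 0.82 (KO) for 4µ8C, 0.57 and 0.58 for 4PBA, and 0.82 for LPS. Each inhibitor acting alone stays open too (r = 0.52 of WT 4µ8C with KO 4PBA), as the labels name no inhibitor group as free of LPS. Genes are not independent replicates in these correlations (10 computed).

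Last, of the 16 genes with a chromosome that differed by genotype under all 4 treatments, 10 lay on chromosome 17 with Bag6 and 6 elsewhere, Pira2, Ide, Gda, Grn, Tgfbi and Serinc3, which stay unexplained. Reads shared among MHC class I copies were excluded as the whole cause, since 5 of the 11 genes left without H2 and Gm names were still on this chromosome (one-sided Fisher's exact p = 0.00012). An effect of losing Bag6 on its nearest neighbours was excluded as the source of the set, since 0 of its 20 nearest tested neighbours were in it. The fixed list of Bag6 neighbours was still called lower in KO cells with 4µ8C (0 of 19 members passing, median log2 fold change -0.15, camera adjusted p = 0.032, adjusted p = 0.46 with an estimated correlation), though not in medium (camera adjusted p = 0.48), LPS or 4PBA (both 0.94). The set's share on the chromosome (one-sided Fisher's exact p = 1.2e-09) and the median distance of 37.5 genes from Bag6, against 142 for the other tested genes there (one-sided permutation p = 0.0016), describe the pattern and do not test its cause. DNA of another strain kept around the targeted allele may explain the chromosome 17 genes and stays open. The 167 genes within 100 of Bag6 that were outside the set and had no H2 or Gm name were not shown to differ more than other windows of the chromosome, as a share of 0.21 gave as large a mean, which decides nothing. No strain variant was examined, and an effect of Bag6 loss on genes farther off stays untested.

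In other splits of the same libraries, fitted alone, chance was excluded for most comparisons. The real split alone (1 of 100 drawn) called as many for KO against WT in medium (864, at most 93 in another), LPS (567, 186) and 4PBA (198, 149). With 4µ8C 2 of 100 did, the real one calling 19 and another 41, which points to a structure of the samples. The real split was also alone for LPS against medium in WT (3883, 5) and KO cells (3102, 2), 4µ8C in WT (3150, 467) and KO cells (3136, 1), and 4PBA in WT (4431, 0) and KO cells (3583, 2). It was alone for rapamycin (2400, 19), 4µ8C against LPS in WT cells (11, 7) and 4PBA against LPS in WT (2984, 2) and KO cells (2164, 55). For 4µ8C against LPS in KO cells the real count was 0 in edgeR, so 100 of 100 splits had to call as many, 1 of them 183, and chance was not excluded.

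In the 7 paired comparisons a split can part all 5 pairs, as the real 1 does, or leave some together. Of the 16 splits that part every pair, the real one alone called as many for LPS (3102, at most 0 in another), 4µ8C (3136, 0) and 4PBA (3583, 1) in KO cells, 4PBA in WT cells (4431, 2), and 4PBA against LPS in WT (2984, 0) and KO cells (2164, 0), where 1 of 16 is the least such splits allow. For 4µ8C against LPS in KO cells all 16 called at most 1 gene in edgeR. The split with 183 therefore left pairs together, so pairing by number may explain it. Blocking within genotype gave 13 genes there.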

How the results depend on the processing

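Settings with position or without the libraries labelled KO replicate 4 were chosen only after the result was seen, as was every setting of the 4 comparisons of an inhibitor with LPS. No named gene's value reversed under any setting.

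With position as a term the genotype counts were 68 in medium, 161 with LPS and 148 with 4PBA. WT 4PBA against WT medium gave 2790, WT 4PBA against WT LPS 1526, the 4PBA interaction 126, and Bag6 with 4PBA -0.91, now past the threshold. WT 4µ8C against WT LPS and the 4µ8C interaction gave 0 in edgeR. In medium and the WT 4PBA comparisons groups and positions coincide, and for KO against WT with LPS in all but 1 library, so the term also widens errors there (median SE from 0.22 to 0.27 in medium and from 0.23 to 0.26 with LPS). For the other counts the cause was not tested. Of values for named genes, 294 of 363 stayed past the threshold. Inner libraries alone gave 173 for KO against WT with 4PBA and 12 for 4µ8C against LPS in KO cells. Outer libraries alone gave 28 for KO against WT with 4µ8C, 2222 for 4µ8C against medium in WT cells, 1142 for rapamycin and 0 for 4µ8C against LPS in WT cells, in edgeR fits of fewer libraries. Inner libraries kept 128 of 140 gene values and outer ones 73 of 105.

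With replicate as a block KO against WT gave 175 with 4µ8C and 115 with 4PBA, the LPS interaction 2, and Bag6 passed in medium (-0.69) and with 4PBA (-0.94). Blocking within genotype gave 13 for 4µ8C against LPS in KO cells and 28 for the LPS interaction. The cause was not tested. Gene values stayed past the threshold in 361 of 363 and 239 of 240 cases.

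Fits of only the groups compared gave 19 for KO against WT with 4µ8C, 198 with 4PBA, 11 for 4µ8C against LPS in WT cells, and 0 in edgeR for 4µ8C against LPS in KO cells and for the LPS interaction. Such fits hold fewer libraries, and 323 of 352 gene values stayed past the threshold. DESeq2 gave 167 for KO against WT with 4µ8C and 83 with 4PBA. It gave 68 and 10 for 4µ8C against LPS in WT and KO cells and 3 for the LPS interaction, and Bag6 with 4PBA passed (-0.91). Without a filter on low counts 4µ8C against LPS gave 13 in WT and 1 in KO cells, with more genes tested, and 333 of 363 gene values passed. DESeq2 and its size factors in edgeR each kept 363 of 363. For DESeq2 the cause was not tested.

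Without the libraries labelled KO replicate 4, KO against WT gave 56 with 4µ8C and 28 with 4PBA, 4µ8C against LPS in KO cells 0 in edgeR, and the 4µ8C interaction 77. Bag6 then passed in medium (-0.86), with LPS (-0.79) and with 4PBA (-1.21). These libraries held the highest Bag6 of their groups, which accounts for the Bag6 values, and for the counts the cause was not tested. TPM in place of CPM put the permutation test of Bag6 with LPS past the threshold (-0.81, exact p = 0.048). Of 720 list tests, 24 passed with an estimated correlation against 164 with the preset one. With position as a term 163 passed, 148 of them among the 164, so list calls were both lost and gained, and the text names only some of them. With replicate as a block 175 passed (163 shared), with DESeq2 size factors 163 (162 shared), without the filter 202 of 810 (155 shared) and by fry 207 (129 shared in direction). The cause was not tested.

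Leaving out 1 library at a time gave 621 to 992 genes for KO against WT in medium, 488 to 723 with LPS, 42 to 124 with 4µ8C and 22 to 61 with 4PBA. Treatments against medium gave 3714 to 3997 (LPS, WT), 3150 to 3619 (LPS, KO), 3654 to 4283 (4µ8C, WT), 2861 to 3353 (4µ8C, KO), 4132 to 4341 (4PBA, WT), 2972 to 3330 (4PBA, KO) and 1990 to 2315 (rapamycin). Against LPS the ranges were 1 to 57 (4µ8C, WT), 0 to 28 (4µ8C, KO, in edgeR), 2461 to 2596 (4PBA, WT) and 2141 to 2356 (4PBA, KO). The interactions gave 1 to 4 for LPS, 86 to 297 for 4µ8C and 425 to 496 for 4PBA. Bag6 ran from -0.85 to -0.51 in medium, -0.79 to -0.39 with LPS, -0.59 to -0.32 with 4µ8C and -1.21 to -0.78 with 4PBA. It passed without KO_medium replicate 4 and without KO_4PBA replicate 4.

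Single libraries moved several counts by more than 1.5 times. For KO against WT with 4µ8C these were WT_4u8C replicates 3 (42) and 4 (61) and KO_4u8C replicates 1 (53) and 4 (58). With 4PBA they were WT_4PBA replicates 1 (24), 2 (29), 3 (31) and 4 (31) and KO_4PBA replicates 1 (23) and 4 (22). For 4µ8C against LPS in WT cells each of the 10 did: WT_LPS replicates 1 to 5 gave 4, 1, 5, 1 and 4, and WT_4u8C replicates 1 to 5 gave 1, 1, 1, 57 and 44. In KO cells KO_LPS replicates 1 and 2 and KO_4u8C replicates 2 and 3 gave 0 in edgeR, KO_4u8C replicate 5 gave 1 and KO_LPS replicate 5 gave 28. The LPS interaction gave 2 without WT_medium replicate 5 and 4 without KO_LPS replicate 1. The 4µ8C interaction moved without WT_medium replicate 1 (113), WT_4u8C replicates 1 (88), 2 (86) and 4 (297), KO_medium replicate 1 (93) and KO_4u8C replicates 2 (96) and 3 (109). Of gene values, 3546 of 3880 stayed past the threshold. Every other total not given here stayed within 1.5 times, but counts in 1 direction moved more. Besides values given with the results, lower genes in medium (238) were 137 without the filter and 400 with replicate as a block. With LPS lower genes (180) were 114 without the filter. With 4PBA lower genes (32) were 19 without the filter. Where the total stayed, higher genes ran from 2 to 28 in the 4µ8C interaction (9) and from 20 to 68 in that of 4PBA (32). Which direction held more genes turned in some settings for LPS and 4µ8C against medium, for rapamycin and for KO against WT with 4µ8C.

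Depth limited Bag6 (8 to 77 counts). Thinned to 1509200 counts per library, the genotype counts were 681 in medium, 507 with LPS, 87 with 4µ8C and 47 with 4PBA.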

Other observations

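Tests of 4PBA against LPS in this part were chosen only after the result was seen. In WT cells with rapamycin, p53 targets and the proteasome were called lower. Of p53 targets, 0 of 18 members were higher and 7 lower (0 and 7 adjusted over the list alone), among them Mdm2 (-1.01 ± 0.24), a ubiquitin ligase for p53. The p53 list had camera adjusted p = 0.0039 (adjusted p = 0.18 with an estimated correlation). Of proteasome genes, 1 of 25 members were higher and 15 lower (1 and 19 adjusted over the list alone), as for Psmb6 (-0.95 ± 0.13). The proteasome list had camera adjusted p = 1.3e-05 (adjusted p = 0.54 with an estimated correlation). Genes that respond to histone deacetylase inhibitors were called higher in WT cells with 4PBA, where 5 of 7 members were higher and 0 lower (5 and 1 adjusted over the list alone). The deacetylase list had camera adjusted p = 0.038 (adjusted p = 0.39 with an estimated correlation). The list was called higher too with 4µ8C in WT cells (camera adjusted p = 0.019, adjusted p = 0.3 with an estimated correlation) and with LPS in KO cells (camera adjusted p = 0.029, adjusted p = 0.34 with an estimated correlation), so its rise was not particular to 4PBA. MHC class II genes were called lower with 4PBA than with LPS in WT cells, where 0 of 15 members were higher and 4 lower (0 and 4 adjusted over the list alone), and the call was lost with position as a term (adjusted p = 0.28). The MHC class II list had camera adjusted p = 0.033 (adjusted p = 0.84 with an estimated correlation). Lysosomal genes were called lower with 4PBA than with LPS in KO cells, where 1 of 24 members were higher and 11 lower (2 and 11 adjusted over the list alone). The lysosomal list had camera adjusted p = 0.0022 (adjusted p = 0.54 with an estimated correlation).

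Camera called 10 lists in none of the 18 comparisons. Among them were partners of Bag6 in its complex and in the insertion of tail-anchored proteins (lowest adjusted p = 0.35, 0 comparisons at an unadjusted p under 0.05, 1 by fry). In medium Get4 (0.85 ± 0.19) was higher in KO cells, and did not pass with position as a term (adjusted p = 0.63). IRE1-dependent decay targets had a lowest adjusted p of 0.16 (0 unadjusted, 1 by fry), LXR targets 0.071 (4 and 7), and aryl hydrocarbon receptor targets 0.3 (0 and 5). Cell cycle genes had 0.13 (1 and 0) and glucocorticoid receptor targets 0.12 (2 and 3). Markers of dendritic cells had 0.23 (0 and 0), of neutrophils 0.15 (2 and 2), of eosinophils 0.31 (0 and 0) and of fibroblasts 0.44 (0 and 0).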
